A study of Homo sapiens with 33 samples.

How the data were processed

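Total RNA was sequenced from 33 libraries of KOLF2.C1 human induced pluripotent stem cells and their HAND1 knockout, in 11 groups of 3. Per the labels' protocols, cells were grown in 6-well plates, libraries were made with a stranded total RNA kit after removal of ribosomal RNA, ERCC spike-in RNA was added, and paired-end reads were taken on a NovaSeq. The labels do not say whether the 3 libraries of a group came from separate cultures or clones, so p-values measure only the spread between these samples, which may be technical.

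The submitters' processing notes name FastQC, Trim Galore, STAR, Salmon and DESeq2 with the GRCh38 build and without versions; the order and settings of these steps are not given in the sources used here. The deposited values were TPM in both tables, although the media table is named as counts: each column summed to 1e6 and the values were not whole numbers. The name of the time course table says TPM. TPM is scaled by the authors to the total and to transcript length, so it keeps no depth, and a gene's TPM falls when other genes take a larger share. No ERCC values were used here. Each of the 2 tables held 33538 genes, with 9 media libraries in one and 24 time course libraries in the other. They were quantified separately, so tests were made only within a table. The number of columns not mapped to a sample was 0.

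Gene symbols were taken by Ensembl identifier from a names table (33113 identifiers matched) and from GENCODE release 29 on GRCh38 (33456 matched, 343 of them named by that annotation only), and 8260 identifiers had no symbol. Coordinates are those of GENCODE 29. Near-identical genes, such as the CGB, MT1, HSPA1 and histone H3 copies, share reads that the quantification may have split in any way. Y-linked genes, XIST and TSIX were left out.

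The plan had a count model for a table of counts and limma-trend for TPM. Because the values were TPM, limma 3.58.1 in R 4.3.3 was run on log2(TPM + 1), keeping genes at 1 TPM or more in at least 3 libraries, with all groups of a table in 1 fit. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, 2-sided, and an absolute log2 fold change of 1 or more. Adjusted p-values of genes are from limma. Genes were named by a rule fixed before the data were examined: HAND1, and in each comparison the 5 largest rises and 5 largest falls among called genes with a mean of 10 TPM or more in the higher group and no overlap between libraries, and in each list up to 4 called members with the largest change and up to 2 that went against the majority. Members of lists named outside that rule are said to be so.

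The 22 gene lists were also fixed before the data were examined: pluripotency, primitive streak, paraxial mesoderm, extra-embryonic mesenchyme, mesenchymal and matrix, epithelial junction, trophoblast, amnion, endoderm, cardiac, endothelial and blood, neural ectoderm, smooth muscle, NODAL and Activin, BMP, FGF and ERK, WNT, HOX, proliferation, stress, mitochondrially encoded and HEK293. They were tested with camera, which compares a list with the other genes, at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. Counts adjusted over the list alone used the members' own p-values and the same fold threshold. Genes called in the media comparison, or in wild type between days 2 and 4, were tested as sets in the knockout comparisons with camera.

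Replicates within a group correlated at 0.964 to 0.996 over log2(TPM + 1), and 0 pairs of libraries held identical values. Same-numbered libraries deviated together in wild type from day 2 to day 3 (correlations 0.163, 0.339 and 0.572 across genes), a link taken from the data, and with the number as a block 3272 genes were called there against 3262. The limma step was tested on simulated data with 200 changed genes of mean log2(TPM + 1) above 4. The rates cover neither low genes nor a shift of most genes. For knockout against wild type on day 6 (16738 genes) limma recovered 98.7% of 79 genes changed by 1.5 on the log2 scale. It recovered 98.4% of 62 changed by 2 and all 59 changed by 3, with 0 unchanged genes called. For BSA against BS (13347 genes) it recovered all of 57, 71 and 72 such genes, with 1 unchanged gene called.

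Alternatives tried were a pseudocount of 0.1, no filter, a filter on a mean of 1 TPM, the replicate number as a block, only the groups compared, each replicate number left out, no fold threshold, median-ratio scaling of TPM, the log2 TPM of RMRP as a covariate, nuclear protein-coding genes alone, and each single library left out. Alternatives that need counts or spike-in values were not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.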

Results

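Gene expression was measured by total RNA sequencing in KOLF2.C1 cells, a human induced pluripotent stem cell line, and in a HAND1 knockout line derived from it. The 33 libraries formed 11 groups of 3, quantified in 2 separate tables. One table held 9 wild-type libraries harvested on day 6 in 3 media. BS contained BMP4, a growth factor of the TGF-beta superfamily, and SU5402, an inhibitor of FGF receptors. BSA-83 was BS with A-83, an inhibitor of the receptors for Activin, NODAL and TGF-beta, and BSA was BS with Activin A. The labels give BS and BSA-83 as trophoblast conditions and BSA as a condition for extra-embryonic mesenchyme, the connective tissue outside the embryo proper. The other table held 24 libraries of wild-type and knockout cells kept in BSA for 2, 3, 4 or 6 days. Values were TPM, transcript abundances scaled to the same total in every library, which keep no record of sequencing depth, so the depth of each library is unknown. Between 11861 and 14235 genes reached 1 TPM in the libraries of the media table, and 12199 to 14819 in those of the time course. Group values are means ± SD over 3 libraries, and log2 fold changes carry their standard error. The labels of the 6 knockout libraries from days 4 and 6 name HEK293T, a human embryonic kidney line, as the cell line, while their titles name the knockout; they were grouped by title.

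HAND1, a basic helix-loop-helix transcription factor of mesoderm and extra-embryonic tissues, is annotated as ENSG00000113196 on chromosome 5, 154474972 to 154478264, minus strand (GRCh38). In wild-type cells it stood at 46.4 ± 6.52 TPM on day 2, 918 ± 32.1 on day 3, 1085 ± 30.2 on day 4 and 406 ± 35.2 on day 6. Knockout cells had 2.51 ± 0.364, 6.47 ± 1.2, 0.836 ± 0.233 and 1.99 ± 0.29 TPM on the same days. No knockout library overlapped a wild-type library of its day, and the log2 fold change ran from -3.75 ± 0.13 on day 2 to -9.22 ± 0.13 on day 4. The labels do not say which part of the gene was deleted, so residual TPM is not evidence of an intact transcript. In the media table HAND1 stood at 12.3 ± 2.26 TPM in BS, 18.1 ± 2.91 in BSA-83 and 281 ± 39.3 in BSA.

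**Figure D1:**
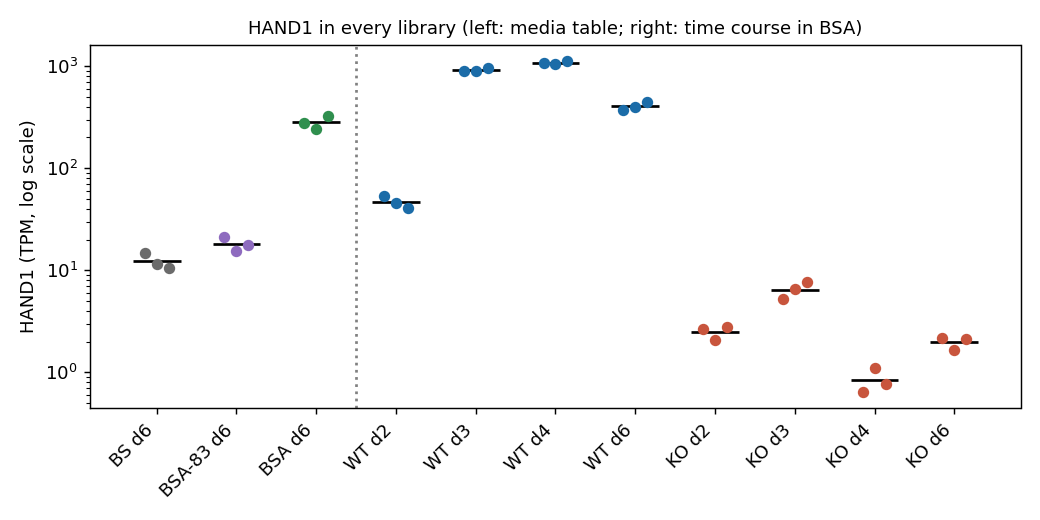
HAND1 in TPM on a log axis for each of the 33 libraries (points), with the group mean as a bar, in the media table (left of the dotted line) and the time course in BSA (right). In the time course wild-type means run from 46.4 TPM on day 2 to 1085 on day 4, and knockout means stay at or under 6.47.

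BSA was compared with BS to ask which genes differ on day 6 when Activin A is added to BMP4 and SU5402. Cells in BSA expressed a broad set of mesenchymal and matrix genes at levels far above those in BS. CDH2, the N-cadherin of mesenchymal cells, stood at 72.6 ± 19.95 against 0.0556 ± 0.0104 TPM, and FN1, the matrix protein fibronectin, at 5479 ± 1225 against 144 ± 2 TPM (adjusted p = 1.6e-10 and 1.56e-10). VIM, an intermediate filament protein, stood at 143 ± 28.2 against 3.27 ± 1.09 TPM, and LUM, the collagen-binding proteoglycan lumican, at 559.9 ± 67 against 31 ± 6.47 TPM. HAND1 itself rose by 4.41 ± 0.14 on the log2 scale. Among genes of lower expression in BSA, HLA-G, the class I molecule of extravillous trophoblast, stood at 65.1 ± 6.48 against 210.0 ± 16.9 TPM and TPPP3 at 19.3 ± 7.86 against 113 ± 2.6 TPM.

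Of 13885 genes tested for BSA against BS, 4007 were called, 3784 higher and 223 lower in BSA. In the mesenchymal and matrix list, 16 of 20 tested members rose, 0 fell and 4 were not called (16 and 0 adjusted over the list alone, camera adjusted p = 0.0037, adjusted p = 0.696 with an estimated correlation). Among smooth muscle and actin genes, 7 of 8 tested members rose, 0 fell and 1 was not called (7 and 0 adjusted over the list alone, camera adjusted p = 0.0037, adjusted p = 0.549 with an estimated correlation). ACTA2 stood at 240.4 ± 28.6 against 11.8 ± 3.18 TPM and TAGLN at 595 ± 71 against 44 ± 2.44 TPM. For the trophoblast list, 8 of 25 tested members fell, 1 rose and 16 were not called (8 and 1 adjusted over the list alone, camera adjusted p = 1.46e-14, adjusted p = 0.241 with an estimated correlation). XAGE2 stood at 514 ± 59.7 against 1148 ± 32 TPM and PAGE4 at 16.5 ± 2.75 against 43.2 ± 5.46 TPM. Of these genes 0 were higher and 19 lower after median-ratio scaling, the list median going from -0.80 to -1.28. In the amnion list, 9 of 14 tested members rose, 0 fell and 5 were not called (9 and 0 adjusted over the list alone, camera adjusted p = 0.787). BAMBI, a BMP pseudoreceptor, stood at 203 ± 29.6 against 8.67 ± 1.46 TPM and IGFBP3 at 1300.2 ± 179.9 against 78.1 ± 5.31 TPM. Of NODAL and Activin targets, 5 of 7 tested members rose, 0 fell and 2 were not called (5 and 0 adjusted over the list alone, camera adjusted p = 0.297). INHBA stood at 29.3 ± 6.4 against 1.24 ± 0.095 TPM and LEFTY2 at 8.59 ± 2.26 against 0.022 ± 0.0197 TPM. Of the extra-embryonic mesenchyme list, 7 of 13 tested members rose, 1 fell and 5 were not called (7 and 1 adjusted over the list alone, camera adjusted p = 0.95, median 1.40 and mean 1.38 log2 with the test pointing down against the other genes). SNAI2 stood at 25.4 ± 4.3 against 0.607 ± 0.157 TPM and PITX1, lower in BSA, at 9.49 ± 1.75 against 31.8 ± 2.82 TPM. The same scaling gave 9 higher and 3 lower in the amnion list and 7 higher and 4 lower in the extra-embryonic mesenchyme list. In the stress list 5 of 15 tested members fell, 2 rose and 8 were not called (5 and 2 adjusted over the list alone, camera adjusted p = 0.00193, adjusted p = 0.241 with an estimated correlation). The fallers were ATF3, CHAC1, DDIT3, TRIB3 and ASNS, genes of the amino acid and unfolded protein responses, while JUN, an AP-1 subunit, stood at 26.5 ± 3.48 against 1.25 ± 0.206 TPM. Cardiac genes included ACTC1, cardiac alpha actin, at 1755 ± 277 against 55.9 ± 11.4 TPM, and 6 of 8 tested members rose, 1 fell and 1 was not called (6 and 1 adjusted over the list alone, camera adjusted p = 0.417). No list call of this comparison held with an estimated correlation. The median log2 fold change of all genes moved from 0.54 to 0.11 with median-ratio scaling, which left 70.0% of 2856 called genes higher, against 94.4% of 4007.

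**Figure D2:**
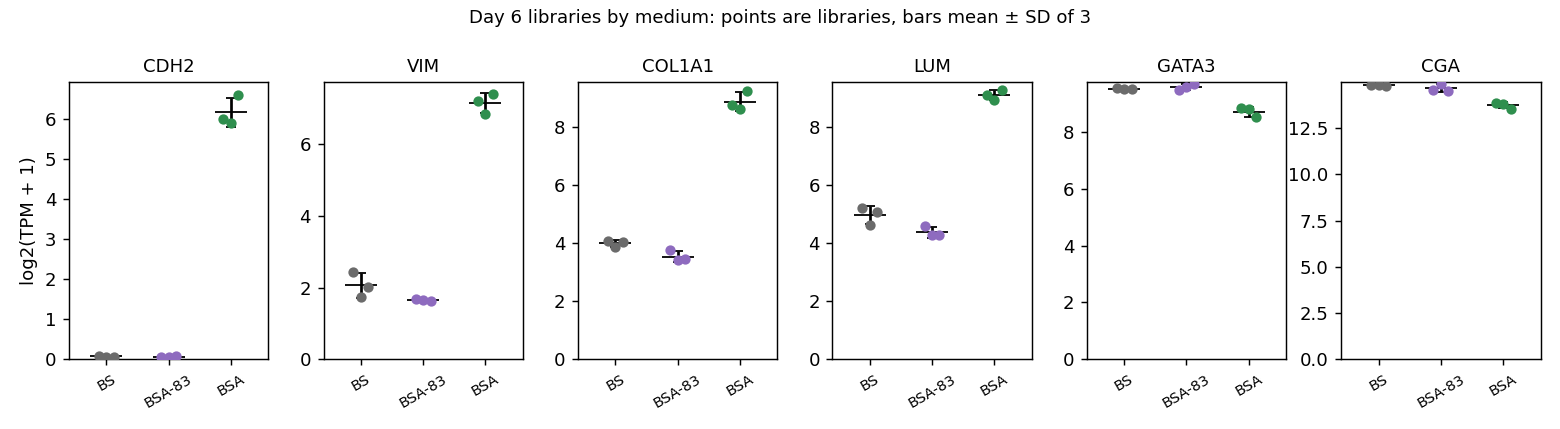
Expression as log2(TPM + 1) of 6 genes on day 6 in the 3 media, with points for libraries and bars for the mean ± SD of 3. CDH2, VIM, COL1A1 and LUM are higher in BSA than in BS and BSA-83, while CGA means run from 13841 TPM in BSA to 28795 in BS.

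BSA-83 was compared with BS to ask what blocking the Activin, NODAL and TGF-beta receptors adds to BMP4 and SU5402. Several smooth muscle and actin genes were lower with A-83. FN1 stood at 52.7 ± 3.2 against 144 ± 2 TPM and ACTA2, smooth muscle alpha actin, at 3.13 ± 0.264 against 11.8 ± 3.18 TPM (log2 fold changes -1.44 ± 0.12 and -1.60 ± 0.15). LIN28A, an RNA-binding protein of stem cells, rose to 93.4 ± 12.8 against 36.4 ± 2.87 TPM, and PAGE4, a placental cancer/testis gene, to 103 ± 10.5 against 43.2 ± 5.46 TPM. SFRP1, a secreted WNT antagonist, fell to 4.59 ± 0.493 against 25.4 ± 1.41 TPM, and CRYAB, a small heat shock protein, rose to 83.2 ± 6.24 against 21.3 ± 0.999 TPM. HAND1 was not called, at 18.1 ± 2.91 against 12.3 ± 2.26 TPM. Of 13885 genes tested, 119 were called, 32 higher and 87 lower in BSA-83. Of the smooth muscle list, 4 of 8 tested members fell, 0 rose and 4 were not called (4 and 0 adjusted over the list alone, camera adjusted p = 0.00696, adjusted p = 0.593 with an estimated correlation). Among NODAL and Activin targets, 2 of 7 tested members fell, 0 rose and 5 were not called (2 and 0 adjusted over the list alone, camera adjusted p = 0.12), and 0 higher and 0 lower with median-ratio scaling. Of trophoblast genes, 1 of 25 tested members rose, 0 fell and 24 were not called (1 and 0 adjusted over the list alone, camera adjusted p = 0.202, median -0.03 and mean 0.08 log2 with the test pointing up against the other genes). The list median moved from -0.03 to 0.05 under median-ratio scaling. For mitochondrially encoded mRNAs, 0 of 13 tested members rose, 0 fell and 13 were not called (0 and 0 adjusted over the list alone, camera adjusted p = 0.00225, adjusted p = 0.593 with an estimated correlation). A pseudocount of 0.1 gave 373 called genes.

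The comparison of BSA with BSA-83 set an added ligand against a blocked receptor. FN1 stood at 5479 ± 1225 against 52.7 ± 3.2 TPM, a log2 fold change of 6.65 ± 0.12, the largest in this comparison among the named genes. SKIL and PMEPA1, feedback inhibitors induced by TGF-beta signalling, stood at 199.6 ± 12.7 against 20.9 ± 4.49 TPM and 18.6 ± 6.54 against 3.73 ± 0.0611 TPM. COL3A1, the chain of type III collagen, stood at 118 ± 20.7 against 0.949 ± 0.303 TPM and ISL1, a LIM homeodomain factor, at 35.5 ± 5.04 against 0.575 ± 0.0622 TPM. Lower in BSA were LIN28A, at 10.4 ± 0.501 against 93.4 ± 12.8 TPM, DPPA3, a maternal-effect gene, at 0.114 ± 0.0782 against 10.3 ± 0.691 TPM, and HLA-G, at 65.1 ± 6.48 against 412 ± 27.2 TPM. Of 13885 genes, 4395 were called, 4108 higher and 287 lower in BSA. Of the NODAL and Activin targets, 6 of 7 tested members rose, 0 fell and 1 was not called (6 and 0 adjusted over the list alone, camera adjusted p = 0.184). In the mesenchymal and matrix list, 16 of 20 tested members rose, 1 fell and 3 were not called (16 and 1 adjusted over the list alone, camera adjusted p = 0.00493, adjusted p = 0.676 with an estimated correlation). The faller was TWIST2, at 1.41 ± 0.25 against 4.12 ± 0.194 TPM. Smooth muscle genes followed, as 7 of 8 tested members rose, 0 fell and 1 was not called (7 and 0 adjusted over the list alone, camera adjusted p = 0.00493, adjusted p = 0.628 with an estimated correlation). For the trophoblast list, 4 of 25 tested members fell, 0 rose and 21 were not called (4 and 0 adjusted over the list alone, camera adjusted p = 1.08e-16, adjusted p = 0.203 with an estimated correlation). Among its members 0 were higher and 19 lower after median-ratio scaling, the list median going from -0.78 to -1.28. In the stress list 3 of 15 tested members rose, 2 fell and 10 were not called (3 and 2 adjusted over the list alone, camera adjusted p = 0.00493, adjusted p = 0.381 with an estimated correlation, median -0.17 and mean 0.09 log2 with the test pointing down against the other genes). With median-ratio scaling 2 were called higher and 5 lower, and the list median went from -0.17 to -0.72. The median log2 fold change of all genes moved from 0.61 to 0.12 with median-ratio scaling, which left 65.4% of 2975 called genes higher, against 93.5% of 4395.

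The wild-type course in BSA was followed day by day, first from day 2 to day 3. Amnion-associated genes increased sharply within this day. VTCN1, an immune checkpoint ligand, rose from 0.217 ± 0.0677 to 246 ± 7.48 TPM, GABRP, a GABA receptor subunit, from 1.63 ± 0.676 to 364 ± 17.6 TPM, and IGFBP3, an insulin-like growth factor binding protein, from 19.9 ± 2.4 to 1614 ± 107 TPM. LUM was listed at 0 on day 2 in all 3 libraries and stood at 120.2 ± 17.6 TPM on day 3. SOX2, a pluripotency factor, fell from 148 ± 2.8 to 12.7 ± 1.69 TPM, and FOXH1, a SMAD cofactor, from 70.4 ± 4.46 to 5.72 ± 2.7 TPM. Of 17128 genes tested in the time course, 3262 were called, 1449 higher and 1813 lower on day 3. In the amnion list 13 of 16 tested members rose, 0 fell and 3 were not called (13 and 0 adjusted over the list alone, camera adjusted p = 5.54e-12, adjusted p = 0.0094 with an estimated correlation). For pluripotency factors, 10 of 15 tested members fell, 0 rose and 5 were not called (10 and 0 adjusted over the list alone, camera adjusted p = 2.32e-05, adjusted p = 0.0194 with an estimated correlation). Among FGF and ERK targets, 8 of 14 tested members rose, 1 fell and 5 were not called (8 and 1 adjusted over the list alone, camera adjusted p = 0.000312, adjusted p = 0.0194 with an estimated correlation). DUSP6, an ERK phosphatase, went from 0.136 ± 0.108 to 16.2 ± 3.05 TPM. Of HOX genes, which pattern the body axis, 6 of 13 tested members rose, 0 fell and 7 were not called (6 and 0 adjusted over the list alone, camera adjusted p = 6.95e-05, adjusted p = 0.0165 with an estimated correlation). HOXB2 reached 48.7 ± 5.06 TPM and HOXA1 19.7 ± 1.58 TPM. Of NODAL and Activin targets, 7 of 12 tested members rose, 1 fell and 4 were not called (7 and 1 adjusted over the list alone, camera adjusted p = 0.00244, adjusted p = 0.0194 with an estimated correlation). NODAL went from 1.66 ± 0.291 to 22.9 ± 5.43 TPM. In the extra-embryonic mesenchyme list, 6 of 18 tested members rose, 0 fell and 12 were not called (6 and 0 adjusted over the list alone, camera adjusted p = 0.000239, adjusted p = 0.0194 with an estimated correlation). Of primitive streak genes, 6 of 12 tested members rose, 1 fell and 5 were not called (6 and 1 adjusted over the list alone, camera adjusted p = 0.00811, adjusted p = 0.0419 with an estimated correlation). CDX1 went from 0.0998 ± 0.173 to 20.5 ± 2.81 TPM. Neural ectoderm genes showed the opposite sign, as 2 of 6 tested members fell, 0 rose and 4 were not called (2 and 0 adjusted over the list alone, camera adjusted p = 0.00371, adjusted p = 0.0247 with an estimated correlation). In the trophoblast list, 11 of 26 tested members rose, 2 fell and 13 were not called (11 and 2 adjusted over the list alone, camera adjusted p = 4.37e-05, adjusted p = 0.0247 with an estimated correlation). NR2F2 and VGLL1 reached 24.5 ± 1.32 TPM and 27.6 ± 4.07 TPM.

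From day 3 to day 4, matrix and contractile genes rose together. TGFBI, a secreted matrix protein, went from 14 ± 0.625 to 1789.5 ± 94.9 TPM, COL3A1 from 1.08 ± 0.0901 to 61.2 ± 2.15 TPM, and TAGLN, the actin-binding protein transgelin, from 43.7 ± 5.23 to 811 ± 76 TPM. ACTC1 went from 321 ± 29.6 to 5192 ± 417 TPM and LUM from 120.2 ± 17.6 to 1509.7 ± 67.9 TPM. CGA, the alpha subunit shared by glycoprotein hormones, rose from 0.384 ± 0.22 to 98.9 ± 4.04 TPM. POU5F1, a core pluripotency factor, fell from 495 ± 27.8 to 133 ± 8.99 TPM, and CDH1, the epithelial cadherin, from 949.8 ± 36.7 to 351 ± 21.8 TPM. HAND1 was not called, at 918 ± 32.1 and 1085 ± 30.2 TPM. Among the genes tested, 2069 were called, 1202 higher and 867 lower on day 4. In the mesenchymal and matrix list, 17 of 22 tested members rose, 0 fell and 5 were not called (17 and 0 adjusted over the list alone, camera adjusted p = 4.76e-19, adjusted p = 1.09e-05 with an estimated correlation). Of smooth muscle and actin genes, 7 of 9 tested members rose, 0 fell and 2 were not called (7 and 0 adjusted over the list alone, camera adjusted p = 2.69e-09, adjusted p = 0.00177 with an estimated correlation). In the cardiac and contractile list, 4 of 9 tested members rose, 0 fell and 5 were not called (4 and 0 adjusted over the list alone, camera adjusted p = 0.00155, adjusted p = 0.0194 with an estimated correlation). MYL7, an atrial myosin light chain, went from 0.393 ± 0.213 to 22.8 ± 3.76 TPM. For pluripotency factors, 7 of 15 tested members fell, 0 rose and 8 were not called (7 and 0 adjusted over the list alone, camera adjusted p = 1.53e-08, adjusted p = 0.0042 with an estimated correlation). Of epithelial junction genes, 6 of 17 tested members fell, 0 rose and 11 were not called (6 and 0 adjusted over the list alone, camera adjusted p = 0.00488, adjusted p = 0.0673 with an estimated correlation).

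From day 4 to day 6, proliferation genes fell while mesenchymal and matrix genes rose. TOP2A and CDK1, of chromosome segregation and mitotic entry, fell from 251 ± 20.8 to 76 ± 17.2 TPM and from 188 ± 14.1 to 58.6 ± 10.7 TPM. CDH2 rose from 25.4 ± 0.715 to 476 ± 80.3 TPM, FBN1, the microfibril protein fibrillin, from 2.06 ± 0.219 to 54.3 ± 6.5 TPM, and HOXA10 from 2.19 ± 0.52 to 91.6 ± 6.71 TPM. CXCL14, a chemokine, rose from 9.39 ± 0.391 to 611 ± 60.1 TPM, and HAND1 fell from 1085 ± 30.2 to 406 ± 35.2 TPM. A total of 2124 genes were called, 1185 higher and 939 lower on day 6. Within the proliferation list, 10 of 15 tested members fell, 0 rose and 5 were not called (10 and 0 adjusted over the list alone, camera adjusted p = 1.69e-10, adjusted p = 0.00581 with an estimated correlation). In the mesenchymal and matrix list, 14 of 22 tested members rose, 4 fell and 4 were not called (14 and 4 adjusted over the list alone, camera adjusted p = 0.000194, adjusted p = 0.0174 with an estimated correlation). The fallers included THY1 at 4.61 ± 2.16 against 41.7 ± 8.83 TPM and COL6A3 at 17.7 ± 3.12 against 123 ± 6.46 TPM. Of the HOX genes, 6 of 13 tested members rose, 2 fell and 5 were not called (6 and 2 adjusted over the list alone, camera adjusted p = 0.00565, adjusted p = 0.054 with an estimated correlation). For the trophoblast list, 11 of 26 tested members rose, 2 fell and 13 were not called (11 and 2 adjusted over the list alone, camera adjusted p = 7.77e-05, adjusted p = 0.0365 with an estimated correlation). CGA went from 98.9 ± 4.04 to 1261 ± 236 TPM and KRT7, a simple-epithelium keratin, from 998 ± 94.1 to 327 ± 18.2 TPM. Of paraxial mesoderm genes, 2 of 6 tested members fell, 0 rose and 4 were not called (2 and 0 adjusted over the list alone, camera adjusted p = 0.00133, adjusted p = 0.0174 with an estimated correlation). DLL1, a NOTCH ligand, went from 8.75 ± 1.17 to 1.1 ± 0.16 TPM. In the amnion list, 6 of 16 tested members fell, 2 rose and 8 were not called (6 and 2 adjusted over the list alone, camera adjusted p = 0.00174, adjusted p = 0.112 with an estimated correlation), and GABRP fell from 989 ± 31.7 to 207 ± 12.3 TPM.

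Over the whole wild-type course, day 6 against day 2, pluripotency genes fell while mesenchymal, smooth muscle and trophoblast genes rose. POU5F1 fell from 1297 ± 374 to 16.1 ± 1.14 TPM and LIN28A from 1991 ± 109 to 22.4 ± 1.88 TPM. COL3A1, at 0.00646 ± 0.0112 TPM on day 2, reached 442 ± 34.6, and ACTA2 rose from 0.176 ± 0.0351 to 462 ± 10.6 TPM. LUM and CGA were listed at 0 in all day 2 libraries and stood at 1635 ± 178 and 1261 ± 236 TPM on day 6. In total 5033 genes were called, 2482 higher and 2551 lower. Of pluripotency factors, 13 of 15 tested members fell, 0 rose and 2 were not called (13 and 0 adjusted over the list alone, camera adjusted p = 7.31e-11, adjusted p = 0.001 with an estimated correlation). In the extra-embryonic mesenchyme list, 14 of 18 tested members rose, 1 fell and 3 were not called (14 and 1 adjusted over the list alone, camera adjusted p = 8.82e-08, adjusted p = 0.00165 with an estimated correlation). SNAI2 and POSTN reached 51.9 ± 3.98 TPM and 57.8 ± 10.2 TPM. In the trophoblast list, 20 of 26 tested members rose, 2 fell and 4 were not called (20 and 2 adjusted over the list alone, camera adjusted p = 9.17e-11, adjusted p = 0.00165 with an estimated correlation), with TFAP2C and TFAP2A, AP-2 factors, falling to 87.4 ± 11 and 94.2 ± 4.09 TPM. For the mesenchymal and matrix list, 18 of 22 tested members rose, 3 fell and 1 was not called (18 and 3 adjusted over the list alone, camera adjusted p = 9.17e-11, adjusted p = 0.000487 with an estimated correlation). Of smooth muscle genes, 7 of 9 tested members rose, 0 fell and 2 were not called (7 and 0 adjusted over the list alone, camera adjusted p = 1.5e-06, adjusted p = 0.00405 with an estimated correlation). Of WNT targets, 3 of 10 tested members rose, 0 fell and 7 were not called (3 and 0 adjusted over the list alone, camera adjusted p = 0.0934). DKK1, a secreted WNT antagonist, went from 0.739 ± 0.549 to 74.7 ± 7.31 TPM. Of stress genes, 8 of 15 tested members rose, 1 fell and 6 were not called (8 and 1 adjusted over the list alone, camera adjusted p = 0.000756, adjusted p = 0.0403 with an estimated correlation), including CDKN1A, the p53-induced inhibitor p21, from 5.27 ± 1.81 to 147 ± 38.1 TPM.

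Knockout and wild-type cells were compared on each day in BSA to ask which genes differ without HAND1. On day 2 the lines already differed, with pluripotency genes among those lower in the knockout. NANOG, a pluripotency factor, stood at 3.71 ± 0.395 against 29.1 ± 6.49 TPM in knockout against wild type, and MKI67, a proliferation antigen, at 16.3 ± 10.8 against 46.7 ± 9.86 TPM. SHISA2, a modulator of WNT and FGF receptors, stood at 54 ± 11.9 against 6.68 ± 1.5 TPM, OTX2, an anterior homeobox factor, at 207 ± 17.5 against 69.5 ± 10.5 TPM, and GDF15, a stress-induced cytokine, at 10.9 ± 4.75 against 1.65 ± 0.572 TPM. The metallothionein gene MT1F stood at 0.186 ± 0.323 against 28 ± 4.71 TPM; the MT1 genes are near-identical copies, so the split of reads among them is uncertain. Of 17128 genes, 707 were called, 215 higher and 492 lower in the knockout. This split rested on single libraries, with 153 higher and 773 lower without knockout replicate 1 and 388 higher and 634 lower without knockout replicate 2. For pluripotency factors, 3 of 15 tested members were lower, 0 were higher and 12 were not called (3 and 0 adjusted over the list alone, camera adjusted p = 0.0219, adjusted p = 0.289 with an estimated correlation). In the mesenchymal and matrix list, 2 of 22 tested members were higher, 1 was lower and 19 were not called (2 and 1 adjusted over the list alone, camera adjusted p = 0.0123, adjusted p = 0.187 with an estimated correlation). CDH2 stood at 11.6 ± 2.31 against 3.63 ± 0.201 TPM. Among trophoblast genes, 2 of 26 tested members were higher, 0 were lower and 24 were not called (2 and 0 adjusted over the list alone, camera adjusted p = 0.0285, adjusted p = 0.289 with an estimated correlation). GATA3 stood at 155 ± 17.2 against 68.7 ± 8.97 TPM. Of mitochondrially encoded mRNAs, 0 of 13 tested members were higher, 0 were lower and 13 were not called (0 and 1 adjusted over the list alone, camera adjusted p = 0.0219, adjusted p = 0.693 with an estimated correlation). RMRP, a small non-coding RNA, took 7.4 ± 4.96% of TPM in knockout and 2.35 ± 1.7% in wild-type libraries. No list call held with an estimated correlation, and median-ratio scaling left 45.2% of 635 called genes higher, against 30.4% of 707.

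On day 3 trophoblast genes were higher and amnion, mesenchymal and NODAL-pathway genes lower without HAND1. GCM1, the transcription factor of syncytiotrophoblast, stood at 98.9 ± 4.73 against 2.42 ± 0.392 TPM in knockout against wild type, and PGF, placental growth factor, at 114 ± 4.02 against 1.74 ± 0.508 TPM. GABRP stood at 0.227 ± 0.0811 against 364 ± 17.6 TPM, a log2 fold change of -8.22 ± 0.15, LUM at 0.365 ± 0.188 against 120.2 ± 17.6 TPM and ACTC1 at 5.45 ± 1.19 against 321 ± 29.6 TPM. A total of 2354 genes were called, 641 higher and 1713 lower. In the trophoblast list, 16 of 26 tested members were higher, 1 was lower and 9 were not called (16 and 1 adjusted over the list alone, camera adjusted p = 3.92e-17, adjusted p = 0.000508 with an estimated correlation). SDC1, a heparan sulfate proteoglycan, stood at 46.1 ± 0.782 against 2.2 ± 0.859 TPM and CGA at 16.5 ± 3.44 against 0.384 ± 0.22 TPM. Of the amnion list, 11 of 16 tested members were lower, 0 were higher and 5 were not called (11 and 0 adjusted over the list alone, camera adjusted p = 1.73e-08, adjusted p = 0.0159 with an estimated correlation). The lower members include HAND1, the deleted gene, here and on the later days. Of NODAL and Activin targets, 10 of 12 tested members were lower, 0 were higher and 2 were not called (10 and 0 adjusted over the list alone, camera adjusted p = 2.31e-07, adjusted p = 0.000655 with an estimated correlation). TDGF1, the NODAL co-receptor, stood at 1.22 ± 0.665 against 23 ± 4.68 TPM and FST, the Activin antagonist follistatin, at 42.8 ± 3 against 309 ± 11.6 TPM. For HOX genes, 6 of 13 tested members were lower, 0 were higher and 7 were not called (6 and 0 adjusted over the list alone, camera adjusted p = 0.00216, adjusted p = 0.0335 with an estimated correlation). HOXB2 stood at 1.61 ± 0.11 against 48.7 ± 5.06 TPM. In the mesenchymal and matrix list, 11 of 22 tested members were lower, 0 were higher and 11 were not called (11 and 0 adjusted over the list alone, camera adjusted p = 0.00165, adjusted p = 0.0335 with an estimated correlation). For primitive streak genes, 7 of 12 tested members were lower, 1 was higher and 4 were not called (7 and 1 adjusted over the list alone, camera adjusted p = 0.016, adjusted p = 0.0747 with an estimated correlation). Of FGF and ERK targets, 6 of 14 tested members were lower, 2 were higher and 6 were not called (6 and 2 adjusted over the list alone, camera adjusted p = 0.595). With median-ratio scaling 2 were called higher and 1 lower, and the list median went from -0.33 to -0.16. RMRP took 3.18 ± 0.504% of TPM in knockout and 0.847 ± 0.748% in wild-type libraries. Median-ratio scaling left 42.1% of 2037 called genes higher, against 27.2% of 2354.

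By day 4 mesenchymal, smooth muscle and NODAL-pathway genes were far lower in the knockout, and trophoblast genes far higher. LUM stood at 0.0156 ± 0.0271 against 1509.7 ± 67.9 TPM, TGFBI at 1.14 ± 0.602 against 1789.5 ± 94.9 TPM and ACTC1 at 5.26 ± 2.49 against 5192 ± 417 TPM. ERVW-1, the fusogenic envelope protein syncytin-1, stood at 432 ± 26.9 against 9.3 ± 1.64 TPM (adjusted p = 1.39e-17), and CGA at 3669 ± 283 against 98.9 ± 4.04 TPM. CDX2, a factor of early trophoblast and hindgut, went the other way and was listed at 0 in all knockout libraries against 3.78 ± 1.64 TPM in wild type.

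Of the 17128 genes tested on day 4, 6764 were called, 1310 higher and 5454 lower in the knockout. Among trophoblast genes, 22 of 26 tested members were higher, 1 was lower and 3 were not called (22 and 1 adjusted over the list alone, camera adjusted p = 1.54e-22, adjusted p = 0.0001 with an estimated correlation). For the mesenchymal and matrix list, 18 of 22 tested members were lower, 1 was higher and 3 were not called (18 and 1 adjusted over the list alone, camera adjusted p = 6.42e-06, adjusted p = 0.00541 with an estimated correlation). VIM stood at 0.548 ± 0.0728 against 195 ± 2.68 TPM, COL6A3 at 0.266 ± 0.204 against 123 ± 6.46 TPM and, higher in the knockout, TWIST2 at 7.97 ± 1.9 against 0.478 ± 0.0104 TPM. Of smooth muscle and actin genes, 8 of 9 tested members were lower, 0 were higher and 1 was not called (8 and 0 adjusted over the list alone, camera adjusted p = 0.000539, adjusted p = 0.0363 with an estimated correlation). CNN1 stood at 6.23 ± 1.18 against 182 ± 4.18 TPM and TPM1 at 222 ± 10.3 against 4657 ± 219 TPM. Of NODAL and Activin targets, 11 of 12 tested members were lower, 0 were higher and 1 was not called (11 and 0 adjusted over the list alone, camera adjusted p = 0.00269, adjusted p = 0.0335 with an estimated correlation). INHBA stood at 0.17 ± 0.0783 against 46.5 ± 2.3 TPM and PMEPA1 at 5.93 ± 2.25 against 49.4 ± 2.91 TPM. In the stress list, 9 of 15 tested members were higher, 3 were lower and 3 were not called (9 and 3 adjusted over the list alone, camera adjusted p = 9.71e-05, adjusted p = 0.0363 with an estimated correlation). GDF15 stood at 756 ± 73.5 against 23.7 ± 0.814 TPM, DDIT3, a factor of the unfolded protein response, at 162 ± 18.3 against 9.87 ± 0.457 TPM and JUN at 0.356 ± 0.0567 against 92.4 ± 3.38 TPM. In the amnion list 11 of 16 tested members were lower, 2 were higher and 3 were not called (11 and 2 adjusted over the list alone, camera adjusted p = 0.00269, adjusted p = 0.142 with an estimated correlation). Of proliferation genes, 9 of 15 tested members were lower, 0 were higher and 6 were not called (9 and 0 adjusted over the list alone, camera adjusted p = 0.0149, adjusted p = 0.169 with an estimated correlation). MKI67 stood at 5.62 ± 2.88 against 93.2 ± 12.6 TPM and PLK1, a mitotic kinase, at 20.4 ± 0.953 against 123 ± 6.32 TPM. Of epithelial junction genes, 4 of 17 tested members were higher, 3 were lower and 10 were not called (4 and 3 adjusted over the list alone, camera adjusted p = 0.0336, adjusted p = 0.142 with an estimated correlation). CDH3, the placental cadherin, stood at 2.35 ± 0.812 against 243 ± 8.96 TPM and CLDN4, a tight junction protein, at 222 ± 17.1 against 68.2 ± 12.4 TPM. Of the junction genes 8 were higher and 2 lower after median-ratio scaling, the list median going from 0.20 to 0.83. The 500 most abundant genes took 58.3 ± 0.37% of TPM in knockout and 49.4 ± 0.87% in wild-type libraries. Median-ratio scaling moved the median log2 fold change of all genes from -0.56 to -0.14 and left 44% of 5707 called genes higher, against 19.4% of 6764.

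On day 6 the knockout cells carried higher levels of trophoblast transcripts and lower levels of matrix and HOX transcripts than wild type. CGA stood at 36260.0 ± 3699.8 against 1261 ± 236 TPM, ERVW-1 at 1590.3 ± 78.8 against 94.7 ± 12.6 TPM, and XAGE2, a placental cancer/testis gene, at 702 ± 19.7 against 19.7 ± 1.79 TPM. CGB5, a beta subunit gene of chorionic gonadotropin, stood at 2008 ± 683 against 44.6 ± 24.5 TPM and CGB8 at 2692 ± 756 against 92.2 ± 56.8 TPM, though the CGB genes are near-identical copies whose reads cannot be assigned with certainty. COL3A1 stood at 3.53 ± 0.503 against 442 ± 34.6 TPM, HOXA10 at 0.0612 ± 0.0738 against 91.6 ± 6.71 TPM and GABRP at 0.2 ± 0.0193 against 207 ± 12.3 TPM. CXCL14 had the largest fall among the named genes, at 1.6 ± 0.481 against 611 ± 60.1 TPM, a log2 fold change of -7.89 ± 0.14 (adjusted p = 8.87e-20). LUM stood at 45.8 ± 8.31 against 1635 ± 178 TPM, with 0.0156 ± 0.0271 TPM in the knockout on day 4, a change that was not tested. CGA and ERVW-1 are list members named here after their values were seen. In GRCh38, CGA lies on chromosome 6, 87085498 to 87095406, LUM on chromosome 12, 91102629 to 91111831, COL3A1 on chromosome 2, 188974320 to 189012746 and GABRP on chromosome 5, 170763350 to 170814047.

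Of 17128 genes on day 6, 7038 were called, 1600 higher and 5438 lower in the knockout. In the trophoblast list, 20 of 26 tested members were higher, 3 were lower and 3 were not called (20 and 3 adjusted over the list alone, camera adjusted p = 5.8e-16, adjusted p = 0.000757 with an estimated correlation), with CDX2 lower at 0.0934 ± 0.144 against 5.4 ± 1.42 TPM. For the mesenchymal and matrix list, 19 of 22 tested members were lower, 1 was higher and 2 were not called (19 and 1 adjusted over the list alone, camera adjusted p = 4.87e-06, adjusted p = 0.00491 with an estimated correlation). COL5A1 stood at 25.2 ± 4.23 against 619 ± 132 TPM and CDH2 at 14.7 ± 4.44 against 476 ± 80.3 TPM. Of HOX genes, 10 of 13 tested members were lower, 0 were higher and 3 were not called (10 and 0 adjusted over the list alone, camera adjusted p = 0.000389, adjusted p = 0.02 with an estimated correlation). Of the extra-embryonic mesenchyme list, 10 of 18 tested members were lower, 1 was higher and 7 were not called (10 and 1 adjusted over the list alone, camera adjusted p = 0.0694). BMP4, a BMP ligand, stood at 3.73 ± 0.14 against 109 ± 6.33 TPM and TBX20, a T-box factor, at 48.5 ± 1.18 against 1.94 ± 1.55 TPM. In the amnion list, 10 of 16 tested members were lower, 3 were higher and 3 were not called (10 and 3 adjusted over the list alone, camera adjusted p = 0.0694). Of smooth muscle genes, 8 of 9 tested members were lower, 0 were higher and 1 was not called (8 and 0 adjusted over the list alone, camera adjusted p = 0.0036, adjusted p = 0.099 with an estimated correlation). In the stress list, 7 of 15 tested members were higher, 2 were lower and 6 were not called (7 and 2 adjusted over the list alone, camera adjusted p = 0.0108, adjusted p = 0.201 with an estimated correlation, median 0.00 and mean 0.77 log2 with the test pointing up against the other genes), where CHAC1, ASNS and TRIB3, targets of the amino acid response factor ATF4, stood at 102 ± 28.8 against 3.53 ± 2.11, 255 ± 4.16 against 27.4 ± 2.51 and 64.4 ± 10.8 against 7.4 ± 2.61 TPM. The list median moved from 0.00 to 0.55 under median-ratio scaling. Of NODAL and Activin targets, 6 of 12 tested members were lower, 0 were higher and 6 were not called (6 and 0 adjusted over the list alone, camera adjusted p = 0.401). LEFTY2 stood at 0.972 ± 0.229 against 45.6 ± 4.02 TPM. Among WNT targets, 6 of 10 tested members were lower, 1 was higher and 3 were not called (6 and 1 adjusted over the list alone, camera adjusted p = 0.279). DKK1 stood at 0.284 ± 0.0606 against 74.7 ± 7.31 TPM and AXIN2 at 75.3 ± 2.59 against 21 ± 0.769 TPM. Median-ratio scaling moved the median log2 fold change of all genes from -0.52 to -0.15 and left 42.5% of 6315 called genes higher, against 22.7% of 7038.

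The remaining lists of day 6 showed no camera call. Of FGF and ERK targets, 6 of 14 tested members were lower, 4 were higher and 4 were not called (6 and 4 adjusted over the list alone, camera adjusted p = 0.481, median -0.17 and mean -0.27 log2 with the test pointing up against the other genes). EGR1 stood at 0.506 ± 0.182 against 16.6 ± 1.31 TPM and DUSP5 at 339 ± 36.8 against 24.7 ± 4.52 TPM. The list median moved from -0.17 to 0.35 under median-ratio scaling. Of BMP targets, 6 of 14 tested members were lower, 2 were higher and 6 were not called (6 and 2 adjusted over the list alone, camera adjusted p = 0.492, median -0.13 and mean -0.54 log2 with the test pointing up against the other genes). GATA2 stood at 430.5 ± 61 against 80.6 ± 11.3 TPM and ID1 at 62.7 ± 9.58 against 279 ± 102 TPM. The list median moved from -0.13 to 0.39 under that scaling. Of epithelial junction genes, 4 of 17 tested members were lower, 2 were higher and 11 were not called (4 and 2 adjusted over the list alone, camera adjusted p = 0.455, median -0.12 and mean -0.34 log2 with the test pointing up against the other genes). With median-ratio scaling 7 were called higher and 3 lower, and the list median went from -0.12 to 0.44. In the proliferation list, 5 of 15 tested members were lower, 2 were higher and 8 were not called (5 and 2 adjusted over the list alone, camera adjusted p = 0.806). PLK1 stood at 6.78 ± 2.52 against 44.6 ± 13.7 TPM and RRM2, a ribonucleotide reductase subunit, at 547 ± 48.9 against 94.7 ± 13.5 TPM. Of the proliferation genes 3 were higher and 3 lower after median-ratio scaling, the list median going from -0.56 to -0.02. For pluripotency factors, 6 of 15 tested members were lower, 1 was higher and 8 were not called (6 and 1 adjusted over the list alone, camera adjusted p = 0.75). SOX2 stood at 0.334 ± 0.186 against 9.27 ± 1.37 TPM. Of endothelial and blood genes, 3 of 11 tested members were lower, 2 were higher and 6 were not called (3 and 2 adjusted over the list alone, camera adjusted p = 0.475, median -0.25 and mean 0.25 log2 with the test pointing up against the other genes). CDH5, the endothelial cadherin, stood at 296 ± 18 against 17.3 ± 2.66 TPM. With median-ratio scaling 3 were called higher and 1 lower, and the list median went from -0.25 to -0.04. Of endoderm genes, 2 of 10 tested members were higher, 2 were lower and 6 were not called (2 and 2 adjusted over the list alone, camera adjusted p = 0.139, median 0.33 and mean -0.09 log2 with the test pointing up against the other genes), or 4 higher and 2 lower with median-ratio scaling, and of cardiac genes 4 of 9 tested members were lower, 1 was higher and 4 were not called (4 and 1 adjusted over the list alone, camera adjusted p = 0.473). For primitive streak genes, 5 of 12 tested members were lower, 2 were higher and 5 were not called (5 and 2 adjusted over the list alone, camera adjusted p = 0.953). The list median moved from -0.12 to 0.09 under median-ratio scaling. Of paraxial mesoderm genes, 1 of 6 tested members was lower, 0 were higher and 5 were not called (1 and 0 adjusted over the list alone, camera adjusted p = 0.75), and of neural ectoderm genes 1 of 6 tested members was higher, 1 was lower and 4 were not called (1 and 1 adjusted over the list alone, camera adjusted p = 0.717, median -0.11 and mean -0.35 log2 with the test pointing up against the other genes). Of genes known from HEK293 cells, 6 of 8 tested members were lower, 1 was higher and 1 was not called (6 and 1 adjusted over the list alone, camera adjusted p = 0.113), of which HOXA10 is also on the HOX list. Of mitochondrially encoded mRNAs, 0 of 13 tested members were higher, 0 were lower and 13 were not called (0 and 0 adjusted over the list alone, camera adjusted p = 0.441, median -0.13 and mean -0.15 log2 with the test pointing up against the other genes). The list median moved from -0.13 to 0.42 under median-ratio scaling.

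**Figure D3:**
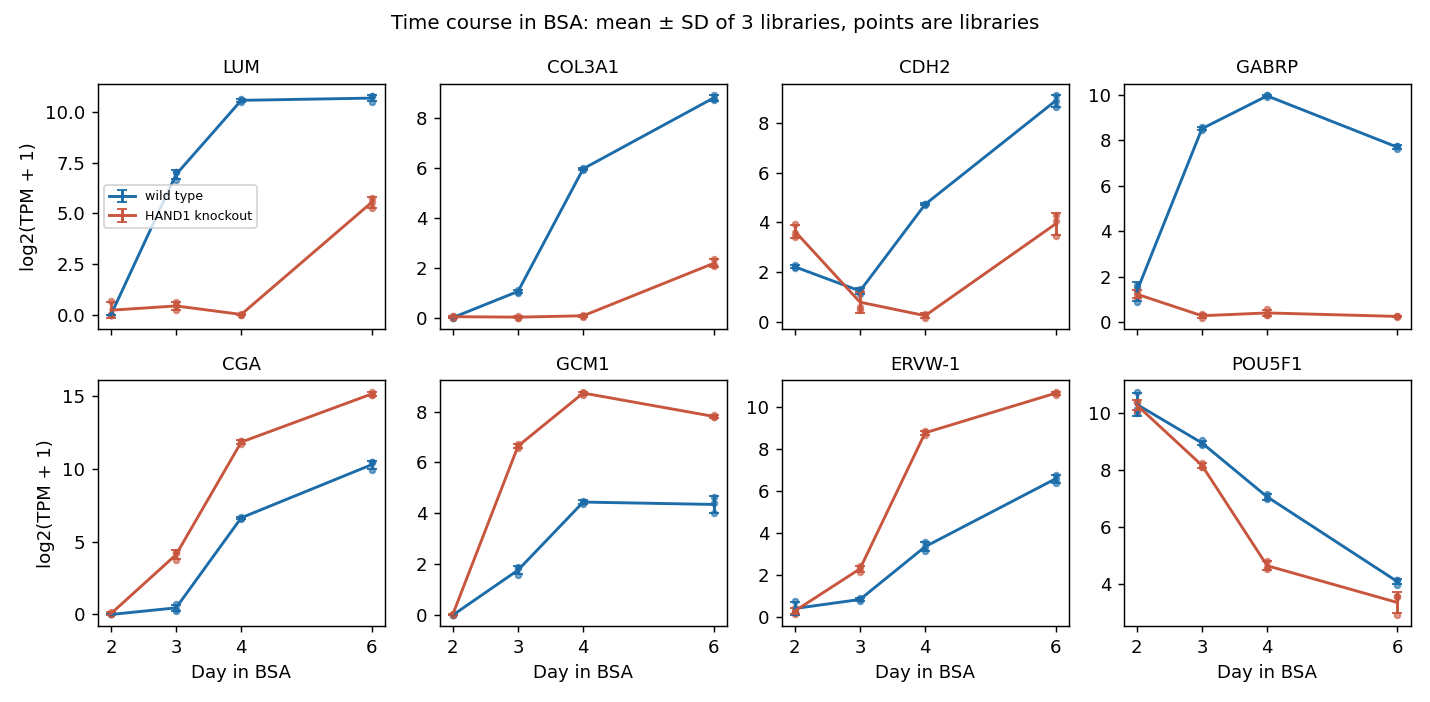
Expression as log2(TPM + 1) of 8 genes by day in BSA, with points for libraries and lines for the mean ± SD of 3, wild type in blue and HAND1 knockout in red. On day 6 knockout and wild-type means are 45.8 and 1635 TPM for LUM, 36260.0 and 1261 for CGA.

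**Figure D4:**
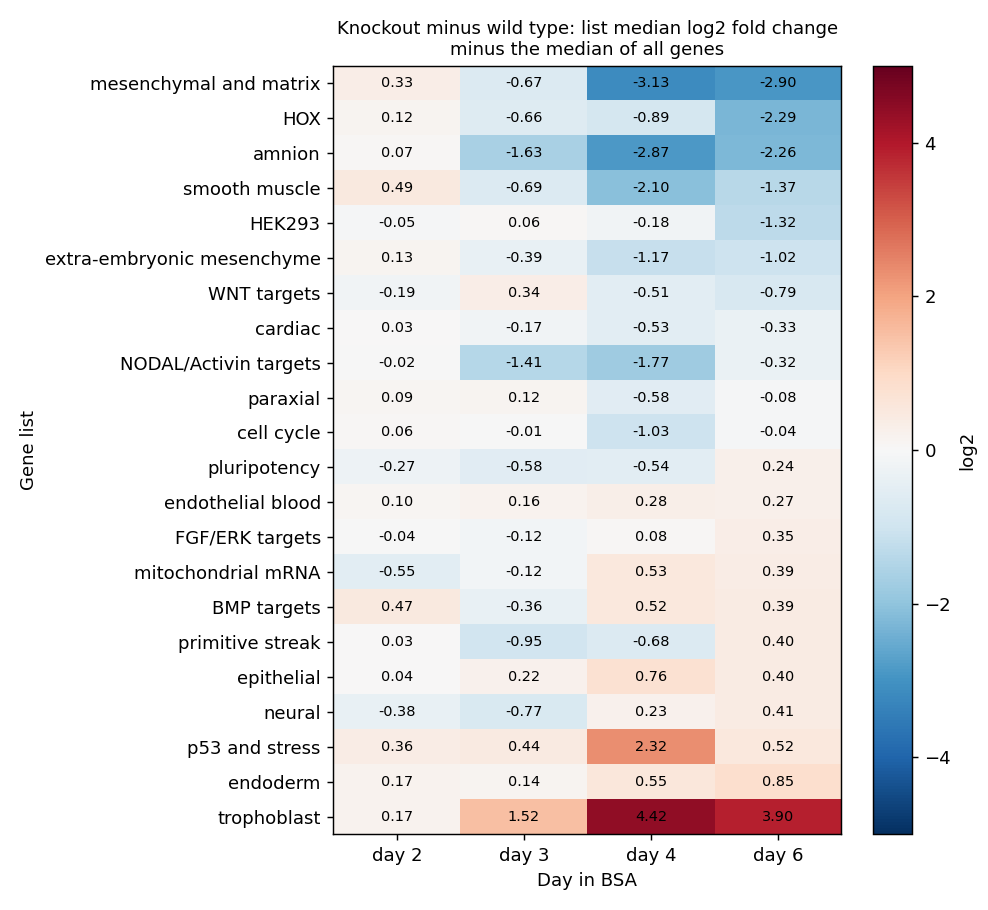
Median log2 fold change of each gene list, knockout minus wild type, after subtracting the median of all genes, by day in BSA. The trophoblast list goes from 0.17 on day 2 to 4.42 on day 4, and the mesenchymal and matrix list from 0.33 to -3.13.

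Within the knockout line, day 6 against day 2 in BSA, trophoblast genes rose and pluripotency genes fell. CGA went from 0.039 ± 0.0676 to 36260.0 ± 3699.8 TPM and CYP19A1, the aromatase that makes estrogens, from 0.128 ± 0.0374 to 1755 ± 48.2 TPM. SOX2 fell from 175 ± 12.9 to 0.334 ± 0.186 TPM and POU5F1 from 1248 ± 144 to 9.5 ± 2.54 TPM. HAND1 was not called, at 1.99 ± 0.29 and 2.51 ± 0.364 TPM. Of 17128 genes, 8147 were called, 2416 higher and 5731 lower on day 6. Of trophoblast genes, 23 of 26 tested members rose, 1 fell and 2 were not called (23 and 1 adjusted over the list alone, camera adjusted p = 1.33e-19, adjusted p = 0.000233 with an estimated correlation). For pluripotency factors, 13 of 15 tested members fell, 0 rose and 2 were not called (13 and 0 adjusted over the list alone, camera adjusted p = 5.34e-05, adjusted p = 0.0356 with an estimated correlation). Of FGF and ERK targets, 9 of 14 tested members rose, 2 fell and 3 were not called (9 and 2 adjusted over the list alone, camera adjusted p = 0.000464, adjusted p = 0.0307 with an estimated correlation). DUSP5 went from 2.83 ± 0.168 to 339 ± 36.8 TPM and ETV5 from 0.174 ± 0.26 to 27.5 ± 3.53 TPM. Of stress genes, 9 of 15 tested members rose, 2 fell and 4 were not called (9 and 2 adjusted over the list alone, camera adjusted p = 0.000233, adjusted p = 0.049 with an estimated correlation). ATF3 went from 12.8 ± 0.512 to 312 ± 27.7 TPM. In the extra-embryonic mesenchyme list 7 of 18 tested members rose, 2 fell and 9 were not called (7 and 2 adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.19 with an estimated correlation). TBX20 went from 0.215 ± 0.194 to 48.5 ± 1.18 TPM and LUM from 0.203 ± 0.352 to 45.8 ± 8.31 TPM. Of mitochondrially encoded mRNAs, 10 of 13 tested members rose, 0 fell and 3 were not called (10 and 0 adjusted over the list alone, camera adjusted p = 0.000589, adjusted p = 0.406 with an estimated correlation). Of HOX genes, 0 of 13 tested members rose, 0 fell and 13 were not called (0 and 0 adjusted over the list alone, camera adjusted p = 0.297). Median-ratio scaling left 44.4% of 7700 called genes higher, against 29.7% of 8147, and moved the median of all genes from -0.49 to -0.16.

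The change from day 2 to day 6 was then set against genotype in an interaction term. Matrix, smooth muscle and HOX genes had lower changes in the knockout, and trophoblast genes higher ones. CXCL14 had an interaction of -9.04 ± 0.20 on the log2 scale, TGFBI of -7.92 ± 0.29 and COL3A1 of -6.65 ± 0.16. MUC15, a placental mucin, had 5.26 ± 0.23 and PRR9 5.31 ± 0.15. Of 17128 genes, 6946 were called, 1982 with a higher and 4964 with a lower change in the knockout. For the mesenchymal and matrix list, 19 of 22 tested members had a lower term, 1 had a higher term and 2 were not called (19 and 1 adjusted over the list alone, camera adjusted p = 7.62e-08, adjusted p = 0.00141 with an estimated correlation). Of HOX genes, 9 of 13 tested members had a lower term, 0 had a higher term and 4 were not called (9 and 0 adjusted over the list alone, camera adjusted p = 3.42e-05, adjusted p = 0.00742 with an estimated correlation). Of smooth muscle genes, 8 of 9 tested members had a lower term, 0 had a higher term and 1 was not called (8 and 0 adjusted over the list alone, camera adjusted p = 0.000131, adjusted p = 0.0266 with an estimated correlation). In the trophoblast list, 19 of 26 tested members had a higher term, 3 had a lower term and 4 were not called (19 and 3 adjusted over the list alone, camera adjusted p = 1.77e-12, adjusted p = 0.00141 with an estimated correlation). Of extra-embryonic mesenchyme genes, 12 of 18 tested, HAND1 among them, had a lower term, 1 a higher term and 5 were not called. Adjusted over the list alone, 12 and 1 were called (camera adjusted p = 0.00964, or 0.116 with an estimated correlation). Median-ratio scaling left 44.2% of 6656 called genes higher, against 28.5% of 6946, and moved the median of all genes from -0.40 to -0.12.

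Genes that differed between media in the other table were followed in the knockout, with no library shared. Of the 3773 tested genes higher in BSA than in BS, which include CDH2, FN1 and LUM, 3113 (82.5%) were lower and 17 higher in knockout than in wild type on day 6 (camera p = 3.78e-44, and p = 0.000202 with an estimated correlation). On day 4, 2826 (74.9%) of them were lower (camera p = 1.95e-33, and p = 0.000778 with an estimated correlation). Median-ratio scaling of both tables made this set smaller, with 1997 tested genes, of which 80.7% were lower on day 6 and 68.9% on day 4 (p = 1.71e-09 and 7.06e-09 with an estimated correlation). Of the 212 genes lower in BSA, among them HLA-G, PAGE4 and XAGE2, 67.5% were higher in the knockout on day 6 and 67.9% on day 4 (p = 5.03e-07 and 1.21e-07 with an estimated correlation). With that scaling the set held 832 tested genes, of which 80.8% and 75.2% were higher on days 6 and 4. The 2080 genes that rose in wild type from day 2 to day 4 gave 1028 lower and 300 higher in the knockout on day 6 (camera p = 0.0207, and p = 0.316 with an estimated correlation), against 790 and 382 of 1990 with the scaling (p = 0.00342 with an estimated correlation). For the 2277 genes that fell over those days, 707 were lower and 212 higher in the knockout on day 6, and camera did not call that set.

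Calls of different days in knockout against wild type share no library. Days 4 and 6 had 3407 lower genes in common, where independent lists would share 1732, and 749 higher genes, against 122. A shift of most genes on both days can raise the lower overlap, which was not recounted after scaling. The lower genes include LUM, TGFBI, COL3A1, GABRP and HAND1, and the higher genes CGA, ERVW-1 and GDF15. Days 2 and 3 shared 221 lower genes against 49.2, with NANOG among them, and 85 higher genes against 8. Between days 2 and 6, 32 higher genes were shared against 20.1. Another 60, among them CXCL14, were higher on day 2 and lower on day 6, against 68.3.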

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

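The tests with RMRP, with the 500 most abundant genes alone, with transcript length and with genes of HEK293 cells were chosen only after the result was seen; the tests with abundant, mitochondrial and non-coding genes, with chromosomes and with splits of the libraries were not.

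What set these results apart is a genotype difference that changed between day 2 and day 6 in the same test, with 6946 called genes. Of 100 splits of the 12 libraries, 9 gave as many, so chance is not excluded by this count; the highest other split gave 8054. The 8 others all kept the genotypes of day 6 whole, while the highest split that mixed day 6 gave 1104. The splits therefore point to a structure of the samples, the day 6 genotype difference.

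CXCL14 had the largest negative term of the genes named for this comparison, -9.04, with 7.42 ± 0.194 against 2.81 ± 0.516 TPM on day 2 and 1.6 ± 0.481 against 611 ± 60.1 TPM on day 6 in knockout against wild type. TGFBI had -7.92, with 5.03 ± 0.768 against 3.84 ± 1.02 TPM on day 2 and 5.87 ± 1.2 against 1309 ± 77 TPM on day 6. IGFBP5 had -7.32, with 2.01 ± 0.443 against 1.8 ± 0.231 TPM on day 2 and 1.26 ± 0.318 against 336 ± 16.7 TPM on day 6. GABRP had -7.31, with 1.37 ± 0.266 against 1.63 ± 0.676 TPM on day 2 and 0.2 ± 0.0193 against 207 ± 12.3 TPM on day 6. CYP26A1, a retinoic acid hydroxylase, had -7.04, with 107 ± 16.1 against 20.2 ± 2.28 TPM on day 2 and 12.1 ± 0.723 against 337 ± 18.8 TPM on day 6. COL21A1, a collagen chain, had 5.84, with 1.43 ± 0.415 against 8.89 ± 0.552 TPM on day 2 and 47 ± 4.3 against 2.54 ± 1.09 TPM on day 6. CGB7 had 5.42, with 0.432 ± 0.175 against 0.7 ± 0.266 TPM on day 2 and 116 ± 34.2 against 2.56 ± 2.29 TPM on day 6. CGB5 had 5.42, with 0.0967 ± 0.084 against 0 TPM on day 2 and 2008 ± 683 against 44.6 ± 24.5 TPM on day 6, and shares near-identical sequence with CGB7. PRR9 had 5.31, with 0 against 0 TPM on day 2 and 2046 ± 131 against 50.8 ± 5.21 TPM on day 6. MUC15 had 5.26, with 3.43 ± 0.938 against 4.48 ± 0.435 TPM on day 2 and 626 ± 44.5 against 19.9 ± 4.54 TPM on day 6.

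On days 4 and 6 most called genes were lower in the knockout, with a median log2 fold change of all genes of -0.56 and -0.52. Composition that goes with RMRP is argued against as the whole cause, since the median stayed at -0.506 on day 6 and -0.527 on day 4 with log2 RMRP as a covariate. A larger share taken by abundant genes is argued against in the same way: without the 500 most abundant genes and the mitochondrial and non-coding genes, the median of the remaining 14982 was -0.461 on day 6 and -0.398 on day 4, and without the 500 alone it was -0.441 and -0.419. Length bias is argued against too, since the fifth of genes with the shortest transcripts had -0.411 on day 6 and -0.501 on day 4, though only as the whole cause, as the fifth with the longest had -0.69 and -0.742. A broader shift of composition, a difference in total RNA per cell, which spike-in values would be needed to measure, and the genotype itself stay open.

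The 6 knockout libraries of days 4 and 6 carry HEK293T in their labels. Of 12 genes known from HEK293 cells, 8 could be tested, and limma called 0 of them higher and 4 lower in knockout cells on day 4 than on day 3. On day 6 against day 3, 1 was higher and 5 were lower, and 7 of the 12 stayed under 1 TPM in all 6 libraries. These libraries had HAND1 at 0.836 ± 0.233 and 1.99 ± 0.29 TPM and CGA at 3669 ± 283 and 36260.0 ± 3699.8 TPM, and of the 641 genes higher in the knockout on day 3, where the labels do not name HEK293T, 301 were higher on day 4 and 209 on day 6, against 49 and 59.9 for independent lists. These values run the way the titles say and argue against HEK293T cells, as far as the assumed list holds. No reference library was used and Y-linked genes were left out, so the line was not settled.

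On day 2 knockout and wild-type libraries already differed, with 707 called genes. Composition that goes with RMRP is argued against as the whole cause, since 474 genes were called with log2 RMRP as a covariate, 407 of them in common with the 707. Gain or loss of a chromosome in the knockout line is argued against: the chromosome that departed most in 1 direction over all 4 days, chromosome 22, had a smallest departure of 0.098 from the median of all genes, where 0.3 was needed. Clone differences and the genotype stay open, as the labels do not say how many clones were used.

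For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05, and 1 of 10 gave as many genes in each. BSA against BS gave 4007 called genes with 0 in the highest other split, BSA-83 against BS 119 with 1, and BSA against BSA-83 4395 with 0. Wild-type days gave 3262 with 3 (day 3 against 2), 2069 with 1 (day 4 against 3), 2124 with 4 (day 6 against 4) and 5033 with 3 (day 6 against 2), and knockout day 6 against 2 gave 8147 with 1. Knockout against wild type gave 707 with 31 on day 2, 2354 with 1 on day 3, 6764 with 0 on day 4 and 7038 with 1 on day 6.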

How the results depend on the processing

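Median-ratio scaling, of gene sets too, the RMRP covariate, nuclear protein-coding genes alone and leaving out single libraries were chosen only after the data were seen; all other alternatives were fixed before the data were examined. No named gene that was called turned its direction under the alternatives in which named genes were followed. Runs without a single library and the run without the fold threshold were not among these. For genes called in neither run the sign was not compared. Under median-ratio scaling 34 of 277 list medians changed sign, 1 of them among the 100 list results that camera called, the stress list of day 6 in knockout against wild type. The majority of a list's calls turned in 9, among them FGF and ERK targets in BSA against BS (3 higher and 1 lower to 2 and 4). Of 1101 named gene results for 311 genes, 11698 of 11874 values under these alternatives kept the call, and for called genes the direction. Calls were lost for 57 gene results with median-ratio scaling, 27 with the RMRP covariate, 30, 21 and 29 without replicates 1, 2 and 3, 7 with a pseudocount of 0.1, 2 with protein-coding genes alone, 2 with only the groups compared and 1 with no filter, and the cause was not tested. Results whose gene was not tested under an alternative are missing from these values. With the filter on a mean of 1 TPM, 1050 of the 1101 results could be followed, and 0 calls were lost. Without replicates 1, 2 and 3, 1017, 1025 and 1018 of the 1101 kept their call, and the rest were lost or not tested. RLE factors, DESeq2, limma-voom and ERCC scaling were not run, as they need counts or spike-in values. Depth is unknown from TPM, so no limit of detection can be given for low genes such as LUM in the knockout on day 4.

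Without the fold threshold, by construction, more genes were called: 11274 (BSA against BS), 3378 (BSA-83 against BS), 11636 (BSA against BSA-83), 8042 (wild-type day 3 against 2), 6026 (wild-type day 4 against 3), 5822 (wild-type day 6 against 4), 10147 (wild-type day 6 against 2), 12661 (knockout day 6 against 2), 4094 (knockout against wild type on day 2), 7445 (on day 3), 11846 (on day 4) and 11803 (on day 6). With a pseudocount of 0.1, BSA-83 against BS had 373 called genes against 119; the cause was not tested. The set of genes higher in wild type on day 4 than on day 2, tested in knockout against wild type on day 6, had p = 0.316 with an estimated correlation and p = 0.11 with sets at adjusted p alone, against 0.0207, and p = 0.00342 with median-ratio scaling; the cause was not tested.

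Leaving out a replicate number from the groups compared gave called genes of 2917 to 3379 (BSA against BS), 105 to 171 (BSA-83 against BS), 3337 to 3751 (BSA against BSA-83), 3099 to 3351 (wild-type day 3 against 2), 2021 to 2056 (wild-type day 4 against 3), 2054 to 2157 (wild-type day 6 against 4), 4940 to 5115 (wild-type day 6 against 2), 7779 to 8273 (knockout day 6 against 2), 592 to 952 (knockout against wild type on day 2), 2129 to 2731 (on day 3), 6677 to 6772 (on day 4), 6876 to 7113 (on day 6) and 6323 to 7181 (the interaction). Leaving out a single library moved no total by over 1.5 times. On day 2 the total of the knockout comparison ran from 513 (without knockout replicate 3) to 1022 (without knockout replicate 2) against 707. Its split moved as given above.

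With the replicate number as a block, the counts were 4009 (BSA against BS), 119 (BSA-83 against BS), 4396 (BSA against BSA-83), 2069 (wild-type day 4 against 3), 2131 (wild-type day 6 against 4), 5037 (wild-type day 6 against 2), 8147 (knockout day 6 against 2), 721 (knockout against wild type on day 2), 2363 (on day 3), 6764 (on day 4), 7043 (on day 6) and 6971 (the interaction). No call of a named gene was lost under the block. Outside wild type from day 2 to day 3, same-numbered libraries did not deviate together in every pair, and the numbers were not taken as pairs.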

Other observations

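The gene families in this part were chosen only after the data were seen, and their p-values are adjusted over the families tested in a comparison. Envelope genes of endogenous retroviruses, several of which encode placental fusion proteins, were called higher in the knockout on day 4 for 5 of 7 and lower for 1 (camera adjusted p = 2.44e-06, adjusted p = 0.0342 with an estimated correlation). In knockout against wild type ERVV-1 stood at 811 ± 37.5 against 39.4 ± 2 TPM, ERVV-2 at 739 ± 34.8 against 33.7 ± 2.48 TPM and ERVFRD-1, which encodes syncytin-2, at 203 ± 5.85 against 5.37 ± 0.597 TPM. ERVH48-1, which encodes an inhibitor of fusion, stood at 33.5 ± 2.82 against 91.6 ± 5.75 TPM, a call that is absent with median-ratio scaling, where 0 were lower. On day 6, 4 were higher and 1 lower, with ERVV-1 at 1468 ± 55.7 against 147 ± 31.6 TPM (camera adjusted p = 0.000127, adjusted p = 0.185 with an estimated correlation). On day 3, 4 were higher and 1 lower, and on day 2, 0 and 1. With an estimated correlation, adjusted p was 0.112 and 0.316.

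In wild-type cells from day 2 to day 3, 9 of 10 keratin genes rose and 0 fell (camera adjusted p = 2.4e-07, adjusted p = 0.00042 with an estimated correlation). KRT16 stood at 42.3 ± 2.82 against 0.0327 ± 0.0566 TPM for day 3 against day 2 and KRT17 at 8.47 ± 0.173 against 0.023 ± 0.0399 TPM. On day 6 KRT16 stood at 1.71 ± 0.342 TPM and KRT17 at 49.3 ± 11.5 TPM. KRT19 was not called, at 397 ± 55.7 against 429 ± 183 TPM on day 2. Metallothionein genes, of which the MT1 copies share reads, were lower in the knockout on day 2 for 5 of 6 (camera adjusted p = 1.41e-06, adjusted p = 0.0417 with an estimated correlation), MT1E standing at 1.03 ± 0.823 against 28.4 ± 12.3 TPM and MT2A at 0.484 ± 0.561 against 10.3 ± 7.65 TPM. On day 3, 4 were higher and 0 lower (camera adjusted p = 0.00618, adjusted p = 0.149 with an estimated correlation), with MT2A at 18.8 ± 4.17 against 4.21 ± 2.02 TPM. On day 4, 0 were higher and 6 lower (camera adjusted p = 0.302), and on day 6, 1 and 3, or 2 and 1 with median-ratio scaling (camera adjusted p = 0.581). Within the knockout line, 9 of 14 cholesterol synthesis genes rose from day 2 to day 6 and 1 fell (camera adjusted p = 0.000139, adjusted p = 0.0361 with an estimated correlation). On day 6 against day 2, SQLE, squalene epoxidase, stood at 534 ± 5.33 against 27.7 ± 4.34 TPM, DHCR7 at 299.8 ± 12.6 against 40.5 ± 6.67 TPM and, falling, DHCR24 at 15.9 ± 0.565 against 156 ± 18.6 TPM. In wild type 6 of them rose and 0 fell over the same days.

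CGA stood at 13841 ± 1554 TPM in wild-type cells in BSA on day 6 in the media table and at 1261 ± 236 TPM in the time course, tables that were quantified separately and not tested against each other. HAND1 stood at 281 ± 39.3 and 406 ± 35.2 TPM in the same groups. The difference was not limited to CGA. In the same order, GCM1 stood at 127 ± 25.4 and 19.7 ± 4.48 TPM and ERVW-1 at 771 ± 101 and 94.7 ± 12.6 TPM. In the other direction, CDH2 stood at 72.6 ± 19.95 and 476 ± 80.3 TPM and LUM at 559.9 ± 67 and 1635 ± 178 TPM. This limits any reading of the media results across to the time course, and the cause was not tested.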
